A study of Mus musculus with 16 samples.

How the data were processed

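Kidneys of 16 labelled mouse samples, 4 per genotype, were dissociated and LTL-binding epithelial cells were sorted by FACS. Libraries were made with the Chromium Next GEM Single Cell 3′ v3.1 chemistry, all per the labels' protocols. The deposited values are UMI counts per gene and barcode, not normalized, for 32285 genes in 1 matrix per genotype. The submitters' processing notes name Cell Ranger 7.0.0 and mm10. The annotation, the intron setting, the cell calling and the deleted parts of both genes are not given in the sources used here. Every barcode ended in the same suffix, so no barcode could be assigned to 1 of the 4 samples of its genotype, and each genotype was treated as 1 library without a test, p-value or standard error. Gene positions are from GENCODE vM21 on GRCm38, the same assembly as mm10.

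Barcodes with at least 500 UMIs, 200 genes and at most 50% mitochondrial UMIs were retained. Doublets were scored with Scrublet per matrix. It called 0 barcodes in WT, 1 in Vhl KO, 0 in Rassf1a KO and 0 in the double KO, so it did not work on these data, no doublets were removed, and doublets remain possible. Retained barcodes of the 4 matrices were clustered together with scanpy 1.11.5 (normalization to the library total, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, no batch integration). Clusters were named from marker lists set before the data were examined. The numerical limits were set after the data were seen and later tightened: a median of at least 2000 non-mitochondrial UMIs, under 30% mitochondrial UMIs, a mean of at least 1000 CPM over proximal tubule markers or 100 CPM over distal markers, and no more markers of another class than of its own among the 10 leading genes. Background-like and mitochondria-rich clusters stayed unnamed and entered comparisons of expression only in the alternatives over all retained barcodes and with the background subtracted.

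Counts were summed over proximal tubule-like cells per genotype, and levels (CPM) are counts scaled to the non-mitochondrial total of each sum. Ratios carry exact conditional binomial intervals, levels exact Poisson intervals and shares exact binomial intervals, all at 95%. A gene with no count in 1 sum was set at a floor of 3 counts and its fold given as a bound. Under an alternative, a sign that such bounds alone gave was not counted as a turn, and list medians were recomputed with those genes left without limit, both added after the data were seen. A list median took members with at least 20 counts over both sums. Its interval came from 500 Poisson redraws and its percentile from 10000 random lists matched over 50 expression bins. A member counted as higher or lower at 1.5-fold with an interval that left out 1. Non-additivity is the log2 level of the double KO less that of each single KO plus that of WT. Correlations across genes used those with at least 20 counts in each of the 4 sums. For shares of cells with a UMI, cells were thinned to 1000 UMIs and shallower cells left out, which kept 224 in WT, 982 in Vhl KO, 1112 in Rassf1a KO and 3578 in the double KO. The share of free RNA was estimated as the ratio of distal tubule marker levels in proximal tubule-like and background-like barcodes.

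Before the data were examined, 27 gene lists and the rule for named genes were set. The rule took the 10 highest and 10 lowest ratios of each knockout against WT and the 6 highest and 6 lowest of the double KO against each single KO, among genes with at least 50 CPM in the higher sum and 50 counts over both. It also took the 10 genes higher and 10 lower in both backgrounds by the smaller absolute ratio, up to 4 members per list with the largest ratio and at least 50 counts, and Vhl and Rassf1. Predicted models, ribosomal, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes were left out of the ranks. For length, not every gene the rule took is given, at most 2 members of most lists are named for their list, and this choice was made after the values were seen. Genes that lead the Malat1-poor cluster are given only where a direction turned with the processing, and some genes the rule took are not reported here. After the data were seen, 4 lists were added (clock genes in 2 phases, sterol biosynthesis and interferon-gamma-inducible GTPases), and the list results given for each comparison were picked after their values were seen: 20, 20, 13, 20, 20 and 3 of 31 lists in Vhl KO, Rassf1a KO and the double KO against WT, the double KO against Vhl KO and against Rassf1a KO and the non-additivity. Of the 30 lists with a percentile, 9, 8, 11, 7, 8 and 5 lay below the central 95% of random lists and 4, 4, 4, 10, 8 and 8 above it in the same order, and the given results are not a complete account.

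Alternatives were the TMM factors of edgeR 4.0.16 and the size factors of DESeq2 1.42.0 (used for scaling only), the total with mitochondrial genes, all retained barcodes, at most 20% mitochondrial UMIs, at least 1000 UMIs, thinning, a minimum of 100 counts or none, resolutions 0.5 and 2.0, clustering of each matrix alone, other thinning depths and Spearman's rho. Added after seeing the data were each proximal tubule-like cluster alone, equal weight of both, subtraction of the background-like profile, the total without the 20 most abundant genes and, for spindle and cell cycle lists, leaving out the resolution 2.0 cluster led by proliferation markers. Interval and ratio code was tested on simulated counts with 200 changed genes per comparison. The interval cover of unchanged genes and the shares of 2-fold and 4-fold higher genes counted as higher were, for Vhl KO against WT (10403 genes) 95.6%, 95% and 100%, for Rassf1a KO against WT (11661 genes) 95.5%, 98% and 100%, for the double KO against WT (12113 genes) 95.6%, 96% and 100%, for the double KO against Vhl KO (12246 genes) 95.6%, 95% and 100%, for the double KO against Rassf1a KO (12795 genes) 95.3%, 96% and 100%. Total counts ranged from 25883853 to 67662335 UMIs per library, and the proximal tubule-like sum of WT, of 4733874 non-mitochondrial UMIs, limits the precision of each ratio against WT. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.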

Results

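Single-cell RNA-seq measured transcripts in proximal tubule epithelium sorted from mouse kidney by binding of Lotus tetragonolobus lectin, which marks the brush border of this segment. The 16 labelled samples fall into 4 genotypes with 4 samples each: wild type (WT), Vhl KO, Rassf1a KO and the KO of both genes (double KO). Vhl encodes the ubiquitin ligase subunit that marks hypoxia-inducible factors (HIF) for degradation, and Rassf1a encodes a microtubule-binding scaffold of the Hippo kinases. The title of the series sets the design in the context of DNA damage, chromosome instability and clear cell renal carcinoma. Each genotype had 1 count matrix whose barcodes carried no mark of the labelled sample, so each genotype is 1 library and no difference between genotypes has a replicate check. Intervals in square brackets are 95% intervals of counting error only.

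The number of barcodes was 13995 in WT, 7669 in Vhl KO, 21973 in Rassf1a KO and 15092 in the double KO, and the total UMI count 25883853 in WT, 26875724 in Vhl KO, 62917010 in Rassf1a KO and 67662335 in the double KO. Barcodes that passed the filters numbered 13867 in WT, 5032 in Vhl KO, 21115 in Rassf1a KO and 10817 in the double KO. Many retained barcodes were shallow, carried a like mixture of tubule transcripts and stayed unnamed as background-like: 96.2% [95.9, 96.5] in WT, 70.7% [69.4, 71.9] in Vhl KO, 87.9% [87.4, 88.3] in Rassf1a KO and 31.5% [30.6, 32.4] in the double KO. A further 1.90% [1.68, 2.15] in WT, 5.31% [4.70, 5.96] in Vhl KO, 6.29% [5.97, 6.63] in Rassf1a KO and 34.4% [33.5, 35.3] in the double KO were mitochondria-rich and also unnamed. The limits that set both classes were chosen after the data were seen. As shares of retained barcodes, proximal tubule-like cells were 1.64% [1.44, 1.87] in WT, 20.3% [19.2, 21.5] in Vhl KO, 5.34% [5.04, 5.65] in Rassf1a KO and 33.2% [32.3, 34.1] in the double KO, which the sort, the filters and these limits can set. Their median depths in UMIs were 15296.5 in WT, 5161.5 in Vhl KO, 14878.5 in Rassf1a KO and 7311 in the double KO. They lay in a cluster rich in the nuclear RNA Malat1, led by Wdr17, Glis1 and Pde4d, and a Malat1-poor cluster led by Apoc3 and Ttr and by the immune gene Cd74. The Malat1-rich cluster held most proximal tubule-like cells of Vhl KO and Rassf1a KO, and the Malat1-poor cluster 50.9% [44.2, 57.5] of those of WT and 56.1% [54.4, 57.7] of those of the double KO. The share of free RNA among their UMIs, estimated from distal tubule markers, was 10.9% in WT, 17.0% in Vhl KO, 18.0% in Rassf1a KO and 30.1% in the double KO. The naming rule had no class of injured proximal tubule, and 34, 185, 107 and 104 cells were non-proximal. This class held distal tubule and collecting duct markers but also sub-clusters of 48 cells led by endothelial genes, 17 led by smooth muscle genes, 41 led by Fst and Lyz2 and 70 that were background-like.

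**Figure D1:**
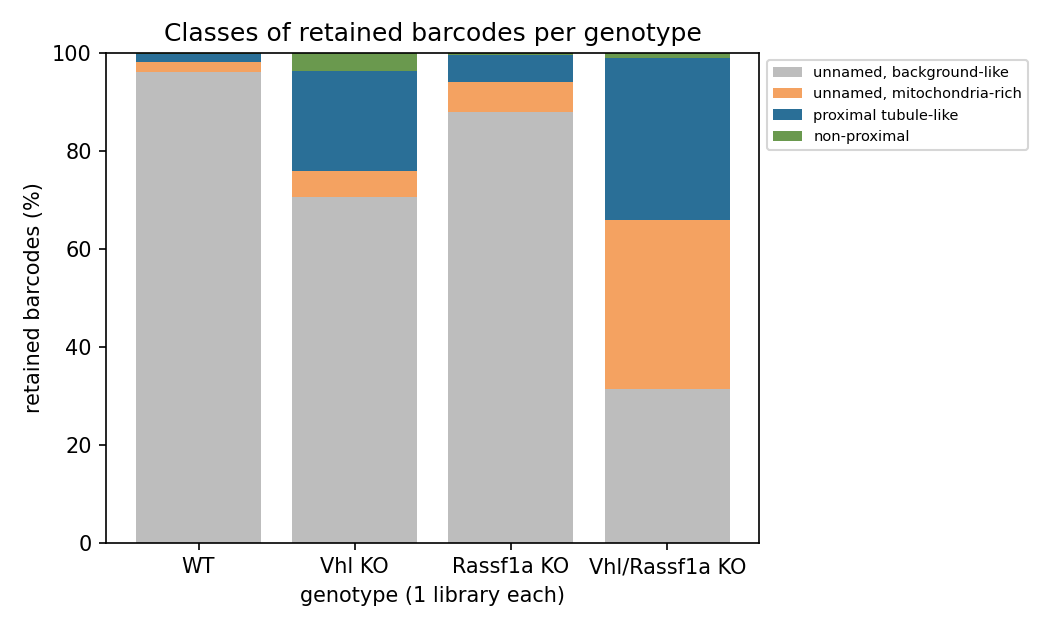
Percent of retained barcodes in each class per genotype, drawn without intervals. Background-like barcodes made up 96.2% in WT and 31.5% in the double KO.

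The targeted genes were read first. Vhl (ENSMUSG00000033933, chromosome 6, 113623959–113631633, plus strand, GRCm38) had scaled counts (CPM, relative to the non-mitochondrial total) in proximal tubule-like sums of 9.93 [7.30, 13.2] in WT, 12.3 [9.66, 15.5] in Vhl KO, 8.63 [7.31, 10.1] in Rassf1a KO and 11.2 [9.97, 12.5] in the double KO. Rassf1 (ENSMUSG00000010067, chromosome 9, 107551555–107562267, plus strand) had CPM of 30 [25.3, 35.4] in WT, 41.0 [36.0, 46.5] in Vhl KO, 45.4 [42.3, 48.7] in Rassf1a KO and 32.2 [30.1, 34.4] in the double KO. Neither was lower in the libraries labelled as its knockout than in WT, although Rassf1 was lower in the double KO than in Vhl KO (0.784-fold [0.680, 0.908]), a direction that turned within the Malat1-rich cluster. The sources used here do not give the deleted parts, and 3′ tags outside a deleted part check nothing, so the labels are taken as given. The median gene shifted by 0.28 (log2) in Vhl KO against WT, 0.17 in Rassf1a KO against WT, 0.17 in the double KO against WT, −0.13 in the double KO against Vhl KO and −0.021 in the double KO against Rassf1a KO. The TMM factors of edgeR and the size factors of DESeq2 brought it near 0. List medians are log2 values relative to this shift, with the percentile among 10000 matched random lists. Counts of members at least 1.5-fold higher or lower beyond counting error, like single-gene folds, use CPM ratios not relative to this shift. A positive shift tilts them upward. No named gene changed direction with the scaling. A direction is said to turn under an alternative only where counts set it, not the floor of 3 counts given to a sum without counts, and thinned medians are read only where at least 50% of a list's measured members remained.

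Loss of Vhl alone was compared with WT to ask what its deletion changes in these cells. HIF targets as a list were not higher, at −0.072 [−0.17, 0.072] (percentile 25.2, 5 of 28 higher, 1 lower), although Ankrd37 was 7.83-fold [3.14, 25.2] and Car9, a hypoxia-induced carbonic anhydrase, 3.27-fold [1.66, 7.01] of WT. Male-biased kidney genes were lower, at −1.72 [−1.85, −1.60] (below all 10000, 1 of 8 higher, 6 lower), and female-biased ones higher, at 1.38 [1.01, 1.65] (percentile 99.97, 4 of 4 higher, 0 lower). Markers of the S3 segment, the last part of the proximal tubule, among them Cyp7b1 and Slc22a30 of the male-biased list, summed to 1555 CPM against 2932 CPM. Cyp4a12a, a male-specific fatty acid hydroxylase (chromosome 4, 115299046–115332815), stood at 4.05 against 119 CPM, 29.4-fold [19.6, 46.3] lower. The organic anion transporter Slco1a1 was 13.6-fold [10.5, 17.8] lower, and the androgen-regulated Kap 5.77-fold [5.68, 5.86] lower. Prolactin receptor Prlr was 2.95-fold [2.14, 4.13] higher.

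Immediate early and dissociation response genes, which dissociation can set, stood at 0.28 [0.063, 0.42] (percentile 99.75, 14 of 31 higher, 1 lower) in Vhl KO. The heat shock gene Hspa1b stood at 5.19-fold [3.23, 8.78] and NF-kB genes at 0.56 [−0.014, 0.69] (percentile 98.5, 5 of 13 higher, 2 lower). Ccl2 had no count in WT and was at least 22.1-fold higher against a floor of 3 counts. Macrophage and monocyte markers summed to 24.5 CPM against 5.91 CPM in the same sums, and the NF-kB median was −0.13 within the Malat1-rich cluster. The p53 list had a median of 0.061 [−0.020, 0.29] (percentile 71.9, 15 of 43 higher, 0 lower), with the cell cycle inhibitor Cdkn1a at 5.63-fold [3.59, 9.24] and Gadd45g at 3.32-fold [2.53, 4.41]. The mitotic spindle list stood at 0.23 [−0.037, 0.65] (percentile 81.2, 6 of 15 higher, 0 lower), where Pttg1, which leads a background-like cluster mostly of this library, was 9.01-fold [5.82, 14.6] and Mad1l1 1.89-fold [1.43, 2.52]. Unfolded protein response genes were lower, at −0.82 [−0.83, −0.63] (below all 10000, 2 of 22 higher, 6 lower), Pdia4 by 2.04-fold [1.68, 2.47], while Ddit3 was 1.81-fold [1.22, 2.75] higher. Interferon genes were lower, at −0.42 [−0.69, −0.16] (percentile 0.0200, 1 of 20 higher, 5 lower), Ifih1 by 1.87-fold [1.30, 2.69], with Irf1 1.91-fold [1.19, 3.14] higher. YAP and TAZ targets stood at 0.13 [0.0010, 0.23] (percentile 88.4, 7 of 22 higher, 1 lower) and the Hippo list at 0.16 [0.055, 0.34] (percentile 92.7, 7 of 18 higher, 0 lower).

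Among metabolic lists, nuclear oxidative phosphorylation genes stood at −0.40 [−0.43, −0.36] (percentile 0.05, 0 of 35 higher, 0 lower) in Vhl KO, with Sdhb 1.49-fold [1.37, 1.61] lower. Mitochondrially encoded genes stood at −0.30 [−0.31, −0.29] (0 of 13 higher, 2 lower), but the filters limit these genes, and over all barcodes their share of UMIs was 46.3% in Vhl KO against 20.4% in WT, so no direction is read. Fatty acid oxidation stood at −0.36 [−0.41, −0.26] (percentile 0.325, 3 of 23 higher, 2 lower), though its members Acot3 and Cyp4a14 were 3.48-fold [2.24, 5.62] and 3.34-fold [2.66, 4.22] higher. Gluconeogenesis stood at −0.36 [−0.39, −0.29] (percentile 8.93, 0 of 9 higher, 0 lower) and glycolysis at −0.16 [−0.20, 0.053] (percentile 22.8, 1 of 15 higher, 0 lower), with Pfkp at 9.43-fold [4.95, 20.2]. Transporters and endocytosis stood at −0.27 [−0.36, −0.20] (percentile 4.34, 7 of 34 higher, 3 lower). Iron handling stood at −0.26 [−0.38, −0.20] (percentile 11.1, 1 of 10 higher, 1 lower). Sex-linked genes, all 4 of them Y-linked, stood at 0.27 [0.14, 0.37] (percentile 92.9, 0 of 4 higher, 0 lower).

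Among the genes highest by fold, the actin-binding Tmsb4x was 6.47-fold [4.63, 9.28] higher. Its ratio was 16.05 within the Malat1-poor cluster and 1.53 [0.896, 2.70] within the Malat1-rich one. In the Malat1-poor cluster macrophage and monocyte markers summed to 41.4 CPM in Vhl KO against 1.76 CPM in WT. Also highest were Iigp1 (4.38 [3.43, 5.67]), Pdk4 (3.94 [3.23, 4.82]), Fosb (3.55 [3.14, 4.03]), Tmem108 (3.40 [2.93, 3.95]), Trpm3 (3.25 [2.52, 4.22]), Hsd3b2 (3.04 [2.85, 3.25]), Zeb1 (2.94 [2.35, 3.69]) and Kcnma1 (2.92 [2.37, 3.63]), of which Iigp1 is an interferon-inducible GTPase, Pdk4 inhibits pyruvate dehydrogenase and Fosb is an AP-1 factor. Tmem108, Trpm3 and Zeb1 turned within the Malat1-poor cluster. Lowest, as folds lower, were Lrp1b (20.8 [16.5, 26.5]), Npas3 (15.1 [10.9, 21.5]), Angptl7 (13.1 [9.76, 17.9]), Cd36 (10.6 [8.64, 13.1]), Col6a6 (10.3 [7.73, 14.1]), Slc7a13 (9.63 [8.34, 11.2]) and Pde1c (6.26 [4.78, 8.30]). Cd36 is a fatty acid transporter and Slc7a13 an amino acid transporter of the last proximal segment. Lrp1b leads a background-like cluster mostly of WT barcodes, Angptl7 leads one mostly of Rassf1a KO barcodes, and Lrp1b turned once the background was subtracted, which left no WT count. Where the interval left out 0, list directions turned within the Malat1-poor cluster for oxidative phosphorylation, interferon, immediate early, iron and sex-linked and after thinning for YAP and TAZ. Other medians moved by over 1.5-fold within the Malat1-poor cluster for female-biased (0.69), over all retained barcodes for female-biased (0.67), with no minimum count for mitotic spindle (0.86) and after thinning for female-biased (0.49).

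Loss of Rassf1a alone was compared with WT for the same purpose. Interferon-gamma-inducible GTPases, which defend cells against vacuolar pathogens, were higher, at 1.22 [0.93, 1.49] (above all 10000, 9 of 11 higher, 0 lower), though by 0.28 within the Malat1-rich cluster and 3.02 within the Malat1-poor one. This list was added after the data were seen. Iigp1 (chromosome 18, 60376027–60392634) stood at 121 against 16.1 CPM, 7.57-fold [6.02, 9.64] higher, and Gbp2 was 4.81-fold [3.27, 7.38] higher. The interferon list as a whole stood at 0.23 [0.059, 0.50] (percentile 82.3, 11 of 32 higher, 2 lower), with Cxcl10 at 3.97-fold [2.55, 6.51], which turned within the Malat1-rich cluster and, from 2 WT counts, after thinning. Class II genes, a list that contains Cd74, stood at 0.40 [−0.0065, 0.56] (percentile 98.0, 3 of 7 higher, 0 lower), with H2-Aa at 1.72-fold [1.29, 2.33] and Ciita at 1.55-fold [1.03, 2.43]. Macrophage and monocyte markers summed to 14.7 CPM against 5.91 CPM. YAP and TAZ targets were higher, at 0.28 [0.19, 0.40] (percentile 98.5, 7 of 21 higher, 1 lower), Nuak2 by 1.92-fold [1.79, 2.07]. The Hippo list stood at 0.20 [0.10, 0.30] (percentile 97.2, 3 of 18 higher, 0 lower), with the kinase Lats2 at 1.68-fold [1.38, 2.07] and Tead1 at 1.56-fold [1.46, 1.67].

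Nuclear oxidative phosphorylation genes in Rassf1a KO stood at −0.38 [−0.42, −0.36] (percentile 0.0100, 0 of 35 higher, 1 lower), with Cycs 1.64-fold [1.56, 1.73] lower, and glycolysis at −0.39 [−0.53, −0.34] (percentile 0.600, 1 of 15 higher, 1 lower). Lipid storage and uptake stood at −0.30 [−0.43, −0.11] (percentile 1.39, 0 of 17 higher, 3 lower), with Cd36 2.85-fold [2.61, 3.11] lower and Plin5 1.86-fold [0.835, 4.86] higher. Fatty acid oxidation stood at −0.23 [−0.28, −0.20] (percentile 3.88, 3 of 23 higher, 1 lower) and gluconeogenesis at −0.18 [−0.22, −0.080] (percentile 32.1, 0 of 9 higher, 0 lower). Male-biased genes were lower, at −0.80 [−0.84, −0.76] (below all 10000, 0 of 9 higher, 5 lower), Slco1a1 by 2.93-fold [2.64, 3.24] and Kap by 1.95-fold [1.93, 1.963], with S3 markers at 2449 CPM against 2932 CPM. Female-biased genes stood at 0.45 [0.27, 0.90] (percentile 91.0, 3 of 5 higher, 0 lower). NRF2 targets stood at −0.31 [−0.37, −0.22] (percentile 0.560, 3 of 19 higher, 2 lower), with Nqo1 1.78-fold [1.39, 2.28] lower and Hmox1 2.25-fold [1.86, 2.74] higher. Unfolded protein response stood at −0.24 [−0.28, −0.15] (percentile 2.5, 3 of 22 higher, 0 lower), iron handling at −0.14 [−0.24, −0.021] (percentile 26.7, 0 of 10 higher, 0 lower) and Y-linked genes at 0.31 [0.16, 0.47] (percentile 94.5, 1 of 4 higher, 0 lower).

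HIF targets stood at −0.19 [−0.24, −0.0062] (percentile 4.69, 3 of 28 higher, 2 lower), with Stc2 2.91-fold [1.67, 5.02] lower and Adm 2.78-fold [1.496, 5.73] higher, the latter turned over all retained barcodes. The p53 list stood at −0.039 [−0.15, 0.089] (percentile 48.1, 6 of 43 higher, 0 lower), with Plk3 at 3.35-fold [2.26, 5.16] and Ddb2 at 2.37-fold [1.47, 4.03]. The mitotic spindle list stood at 0.13 [−0.056, 0.47] (percentile 73.8, 3 of 17 higher, 1 lower). Other genes highest by fold were Grid1 (4.42 [3.47, 5.71]), Gbp6 (3.15 [2.54, 3.95]), Zeb1 (2.90 [2.37, 3.59]), Maml3 (2.56 [2.08, 3.19]), Fosb (2.45 [2.18, 2.76]), Vgll4 (2.44 [2.05, 2.92]), Nfkbiz (2.42 [2.001, 2.94]) and P3h2 (2.402 [2.27, 2.54]). Zeb1 turned over all retained barcodes and Nfkbiz within the Malat1-poor cluster. Lowest, as folds lower, were Lrp1b (10.8 [9.70, 12.1]), Pde1c (7.06 [5.85, 8.55]), Il31ra (6.44 [6.15, 6.75]), Bloc1s1 (3.59 [3.06, 4.21]), Cyp4a12a (3.27 [2.91, 3.66]), Sec61a1 (3.09 [2.74, 3.50]) and Gstp1 (2.91 [2.51, 3.38]). Lrp1b, Il31ra and Sec61a1 lead background-like clusters mostly of WT, Gstp1 and Bloc1s1 one mostly of Vhl KO, and Iigp1 and Gbp6 one mostly of Rassf1a KO, and Sec61a1 turned once the background was subtracted, which left no WT count. Where the interval left out 0, list directions turned within the Malat1-poor cluster for gluconeogenesis, lipid storage, NRF2, iron and sex-linked, over all retained barcodes for gluconeogenesis, fatty acid oxidation, interferon and iron and after thinning for HIF targets and unfolded protein response. Other medians moved by over 1.5-fold within the Malat1-poor cluster for interferon (1.83) and female-biased (1.60).

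**Figure D2:**
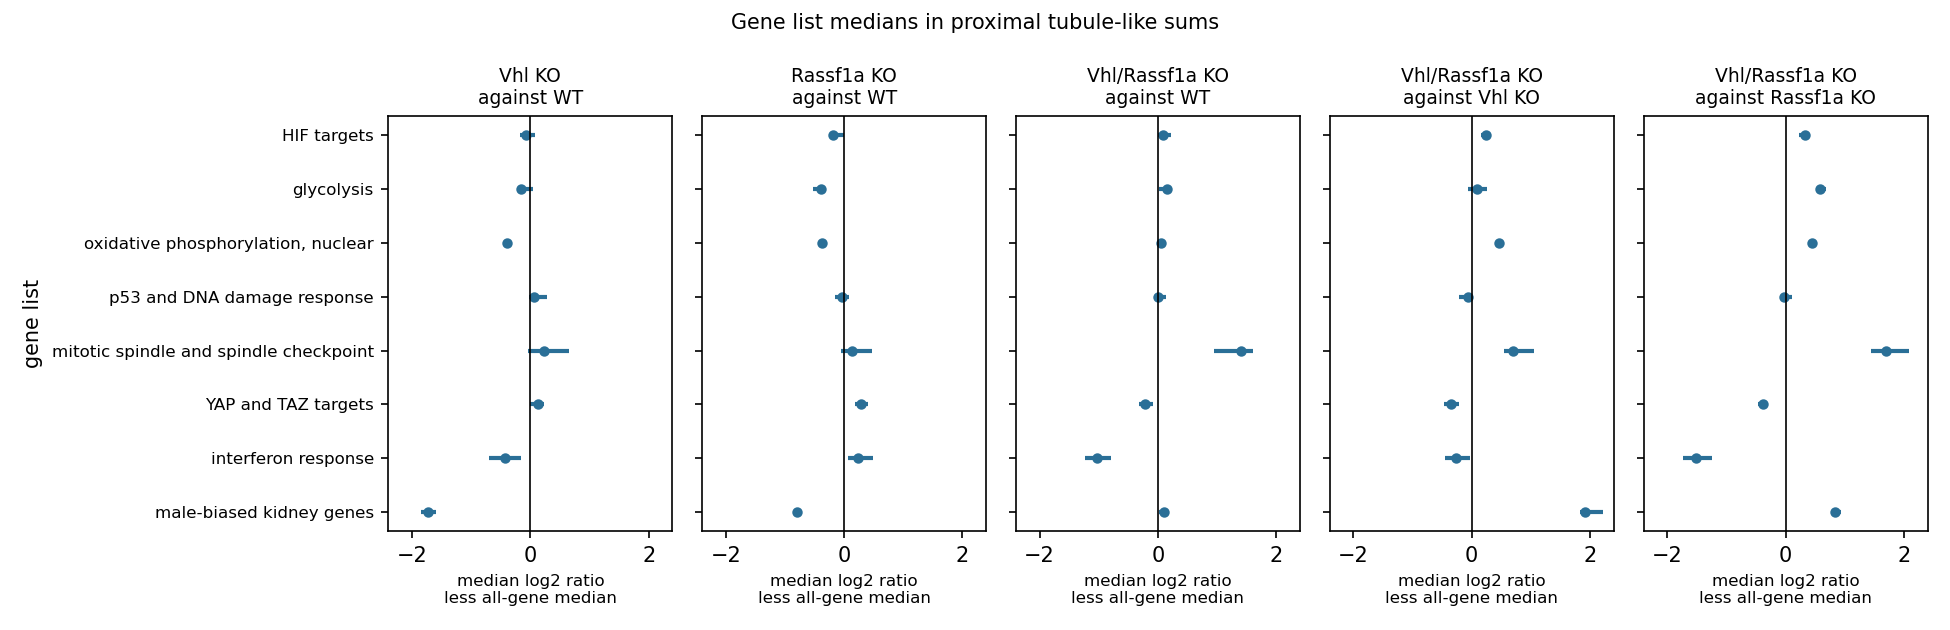
Median log2 ratio of 8 gene lists relative to the all-gene median in 5 comparisons, with 95% counting intervals. The mitotic spindle list stood at 1.40 in the double KO against WT and the interferon list at −1.02, and the first at 0.79 without the cluster led by Top2a.

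Loss of both genes was compared with WT to ask what the joint deletion changes. In the summed counts mitotic spindle genes stood at 1.40 [0.95, 1.61] (above all 10000, 21 of 35 higher, 0 lower) and cell cycle genes at 0.46 [0.37, 0.65] (above all 10000, 16 of 32 higher, 0 lower). At resolution 2.0 a cluster led by Top2a, Mki67, Hmmr and Cenpf held 37 proximal tubule-like cells of the double KO, or 1.03%, 4 of Vhl KO, 1 of Rassf1a KO and 0 of WT. Without it the spindle median was 0.79 and that of cell cycle genes 0.39. The spindle motor Kif11 had 154 counts against 1, 26.9-fold [4.76, 1070.3], and Cdc20, also of the spindle list, 123 against 1, 21.5-fold [3.79, 856]. Topoisomerase Top2a had no count in WT and was at least 21.6-fold higher against a floor of 3 counts, and Rrm2, of nucleotide synthesis, was 11.02-fold [3.71, 53.9] higher. The WT sum was the smallest, so these ratios rest on few WT counts, and after thinning none of these 4 genes had a WT count. Cells with at least 3 UMIs of 6 proliferation markers made up 1.32% [0.272, 3.80] in WT, 1.27% [0.678, 2.16] in Vhl KO, 0.355% [0.0967, 0.905] in Rassf1a KO and 1.56% [1.18, 2.02] in the double KO without thinning, at median depths of 15296.5, 5161.5, 14878.5, 7311 UMIs. After thinning to 1000 UMIs they were 0% in WT, 0.305% [0.0630, 0.890] in Vhl KO, 0% in Rassf1a KO and 0.475% [0.277, 0.760] in the double KO, and in background-like barcodes 0.0111% [0.000281, 0.0618] in WT, 0% in Vhl KO, 0.0118% [0.00143, 0.0425] in Rassf1a KO and 0.0994% [0.0120, 0.359] in the double KO, at median depths before thinning of 1307, 1163.5, 1499, 1152.5. By 3 counts, these shares of 0 limit cells seen with 3 such UMIs at this depth, not proliferating cells, to 1.34% in WT and 0.270% in Rassf1a KO, and to 1.08% of background-like barcodes in Vhl KO.

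Interferon genes were lower in the double KO than in WT, at −1.02 [−1.24, −0.80] (below all 10000, 0 of 28 higher, 16 lower), Gbp2 by 4.17-fold [2.44, 7.04] and Ifit3 by 3.99-fold [2.42, 6.51]. Injury and dedifferentiation genes were lower, at −0.53 [−0.74, −0.39] (below all 10000, 2 of 26 higher, 10 lower), the complement gene C3 by 13.6-fold [9.41, 19.9] and Akap12 by 7.76-fold [5.12, 11.9]. YAP and TAZ targets stood at −0.21 [−0.31, −0.091] (percentile 0.410, 1 of 23 higher, 3 lower), with Nuak2 2.69-fold [2.47, 2.93] lower and the mitotic Birc5 4.62-fold [1.93, 14.5] higher. HIF targets stood at 0.085 [0.0015, 0.23] (percentile 90.8, 8 of 31 higher, 2 lower), with Adm at 3.53-fold [1.93, 7.17], which turned over all retained barcodes, and Anln, a cytokinesis gene also in the spindle list, at 14.9-fold [2.60, 594] from 1 WT count. Glycolysis stood at 0.15 [0.013, 0.19] (percentile 93.3, 2 of 17 higher, 2 lower), with Pfkp at 8.53-fold [4.60, 17.9] and Eno1 2.32-fold [2.11, 2.55] lower. Gluconeogenesis stood at 0.066 [0.022, 0.12] (percentile 71.4, 0 of 9 higher, 0 lower), transporters at 0.084 [0.029, 0.11] (percentile 95.4, 6 of 35 higher, 0 lower), with the amino acid transporter Slc6a19 2.13-fold [2.001, 2.28] higher, and proximal tubule transcription factors at 0.084 [0.026, 0.23] (percentile 87.7, 3 of 14 higher, 0 lower), with Nr1h4 at 1.85-fold [1.74, 1.97]. The p53 list stood at 0.0088 [−0.069, 0.14] (percentile 60.3, 8 of 47 higher, 1 lower), with Btg2 2.42-fold [1.84, 3.18] lower.

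The highest gene by fold was Catspere2, annotated as a sperm ion channel subunit (chromosome 1, 177983423–178172704), at 64.3 against 8.24 CPM, 7.80-fold [5.68, 11.01] higher. Others were Cyp2d12 (5.92 [4.87, 7.27]), Grid1 (5.28 [4.16, 6.80]), Car3 (3.88 [3.02, 5.06]), Pde1a (3.78 [3.49, 4.10]), Mdk (3.11 [2.72, 3.57]), Glrx (2.69 [2.21, 3.32]) and Nr1d2 (2.63 [2.26, 3.07]), where Car3 is a carbonic anhydrase and Mdk the growth factor midkine. Lowest, as folds lower, were Lrp1b (21.3 [18.9, 24.1]), Gstp1 (18.6 [14.9, 23.5]), Angptl7 (15.6 [13.2, 18.5]), Npas3 (13.5 [11.4, 16.03]), Il31ra (8.39 [8.03, 8.77]), Pde1c (4.93 [4.24, 5.73]), Npas2 (3.11 [2.78, 3.47]) and Prxl2b (2.92 [2.505, 3.40]). Mdk, Gstp1, Lrp1b, Il31ra and Angptl7 lead background-like clusters mostly of 1 library. Ttr, Apoc3, Cd74 and Apoe met the rule for named genes in 1 or more comparisons but lead the Malat1-poor cluster, so their differences are not given except where a direction turned with the processing. Where the interval left out 0, list directions turned within the Malat1-rich cluster for HIF targets, glycolysis and gluconeogenesis, at 20% mitochondrial UMIs or less for transporters and with the background subtracted for glycolysis and gluconeogenesis. Other medians moved by over 1.5-fold within the Malat1-poor cluster for interferon (−0.20), within the Malat1-rich cluster for mitotic spindle (0.58) and at 20% mitochondrial UMIs or less for mitotic spindle (0.79).

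Loss of Rassf1a on the Vhl-deleted background was read from the double KO against Vhl KO. Male-biased genes were higher, at 1.91 [1.82, 2.22] (above all 10000, 7 of 9 higher, 1 lower), and female-biased genes lower, at −0.86 [−1.01, −0.71] (percentile 0.205, 1 of 5 higher, 4 lower), with S3 markers at 3121 CPM against 1555 CPM. Cyp4a12a was 14.2-fold [9.50, 22.2] higher, Slco1a1 8.94-fold [6.97, 11.7] and Cyp2e1 4.95-fold [4.60, 5.34]. Immediate early genes were lower, at −0.71 [−0.78, −0.56] (below all 10000, 0 of 31 higher, 18 lower), Hspa1a by 7.43-fold [5.65, 9.80]. Injury genes were lower, at −0.74 [−0.99, −0.66] (below all 10000, 1 of 28 higher, 20 lower), and Ccl2, with 83 counts in Vhl KO and none in the double KO, was at least 126-fold lower, while Havcr1, the tubule injury marker KIM-1, had 111 counts against 1, 24.3-fold [4.27, 968]. Macrophage and monocyte markers summed to 16.8 CPM in the double KO against 24.5 CPM. Interferon genes stood at −0.26 [−0.46, −0.021] (percentile 4.85, 0 of 26 higher, 8 lower), the GTPases at −1.32 [−1.53, −0.69] (below all 10000, 0 of 10 higher, 7 lower), with Iigp1 7.08-fold [6.06, 8.29] lower, and class II genes, Cd74 among them, at −0.99 [−1.15, −0.70] (percentile 0.0100, 0 of 7 higher, 6 lower), with Ciita 2.91-fold [1.60, 5.18] lower.

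Oxidative phosphorylation genes stood at 0.46 [0.43, 0.49] (above all 10000, 0 of 35 higher, 0 lower), and at 0.014 within the Malat1-poor cluster, with Sdhb at 1.49-fold [1.40, 1.59]. Unfolded protein response stood at 0.41 [0.29, 0.49] (percentile 99.98, 2 of 23 higher, 2 lower), gluconeogenesis at 0.40 [0.35, 0.44] (percentile 92.6, 0 of 9 higher, 0 lower), fatty acid oxidation at 0.23 [0.17, 0.32] (percentile 91.3, 3 of 23 higher, 2 lower) and lipid storage at 0.24 [0.12, 0.38] (percentile 97.8, 2 of 18 higher, 4 lower), with Cd36 7.53-fold [6.20, 9.23] higher. HIF targets stood at 0.24 [0.16, 0.33] (percentile 98.7, 6 of 31 higher, 2 lower), although Ankrd37 was 2.95-fold [2.01, 4.27] lower. The mitotic spindle list stood at 0.70 [0.55, 1.06] (above all 10000, 13 of 36 higher, 1 lower), or 0.014 without the cluster led by Top2a, with Ccnb1 at 4.16-fold [1.35, 20.8] from 3 counts in Vhl KO and Pttg1 8.85-fold [7.12, 11.05] lower. The p53 list stood at −0.057 [−0.22, 0.0031] (percentile 23.9, 1 of 47 higher, 13 lower), with Cdkn1a 3.15-fold [2.55, 3.88] lower. YAP and TAZ targets were lower, at −0.36 [−0.46, −0.21] (percentile 0.0200, 0 of 23 higher, 9 lower), Ptpn14 by 3.75-fold [2.07, 6.76]. The Hippo list stood at −0.15 [−0.25, −0.068] (percentile 4.89, 0 of 18 higher, 2 lower). Iron handling stood at 0.21 [0.14, 0.30] (percentile 85.2, 1 of 10 higher, 1 lower) and Y-linked genes at −0.20 [−0.28, −0.12] (percentile 10.5, 0 of 4 higher, 0 lower). Further genes by fold were Col6a6 and Slc7a13, 7.55-fold [5.73, 10.1] and 6.25-fold [5.44, 7.20] higher, and, as folds lower, Gstp1 (15.2 [12.1, 19.2]), Vmn1r18 (6.65 [5.59, 7.92]), Il31ra (6.41 [6.13, 6.70]), Tmsb4x (4.78 [4.07, 5.62]) and Erbb4 (3.82 [3.32, 4.38]), of which Gstp1 and Il31ra lead background-like clusters. Where the interval left out 0, list directions turned within the Malat1-poor cluster for fatty acid oxidation, iron and sex-linked, within the Malat1-rich cluster for lipid storage and unfolded protein response and with equal weight of the 2 clusters for lipid storage and iron. Other medians moved by over 1.5-fold within the Malat1-poor cluster for injury (−1.40) and female-biased (−0.099), within the Malat1-rich cluster for mitotic spindle (0.098) and female-biased (−1.84), over all retained barcodes for injury (−1.56) and interferon (−0.93) and after thinning for class II (−0.31).

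Loss of Vhl on the Rassf1a-deleted background was read from the double KO against Rassf1a KO. HIF targets were higher, at 0.33 [0.23, 0.40] (percentile 99.95, 9 of 31 higher, 1 lower), Igfbp1 by 2.85-fold [2.25, 3.66]. Glycolysis genes were higher, at 0.58 [0.53, 0.69] (above all 10000, 8 of 17 higher, 2 lower), Aldoc by 3.66-fold [1.78, 8.46] and Pfkp by 2.20-fold [1.83, 2.67]. Mitotic spindle genes stood at 1.70 [1.44, 2.08] (above all 10000, 26 of 36 higher, 1 lower), or 0.62 without the cluster led by Top2a, with Cenpf at 23.1-fold [11.03, 58.0] and Ccnb1 at 18.4-fold [4.87, 156] from 2 counts in Rassf1a KO, and cell cycle genes at 0.72 [0.59, 0.89] (above all 10000, 17 of 32 higher, 1 lower), with Top2a at 19.9-fold [11.3, 38.9] and Mki67 at 18.5-fold [10.9, 34.1]. Interferon genes were lower, at −1.51 [−1.74, −1.25] (below all 10000, 0 of 31 higher, 21 lower), Gbp2 by 20.1-fold [14.4, 28.9] and Gbp3 by 15.6-fold [8.40, 32.2]. Their median was −0.59 within the Malat1-rich cluster and −2.48 within the Malat1-poor one. Class II genes, Cd74 among them, stood at −1.30 [−1.54, −1.09] (below all 10000, 0 of 7 higher, 7 lower), with Ciita 7.27-fold [4.97, 10.9] lower.

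Oxidative phosphorylation stood at 0.44 [0.42, 0.46] (above all 10000, 4 of 35 higher, 0 lower), with Sdhd at 1.79-fold [1.69, 1.90], fatty acid oxidation at 0.23 [0.17, 0.27] (percentile 97.4, 2 of 23 higher, 0 lower) and gluconeogenesis at 0.25 [0.21, 0.27] (percentile 83.1, 0 of 9 higher, 0 lower). Male-biased genes were higher, at 0.83 [0.79, 0.95] (above all 10000, 6 of 9 higher, 1 lower), Acsm3 by 2.65-fold [2.47, 2.85], with S3 markers at 3121 CPM against 2449 CPM. Female-biased genes stood at −0.47 [−0.73, −0.32] (percentile 3.54, 0 of 5 higher, 2 lower). YAP and TAZ targets were lower, at −0.38 [−0.47, −0.32] (percentile 0.0200, 3 of 24 higher, 9 lower), Nuak2 by 5.17-fold [4.90, 5.46], although Birc5 was 7.10-fold [3.93, 14.1] higher. The Hippo list stood at −0.083 [−0.17, −0.030] (percentile 16.4, 0 of 18 higher, 1 lower). Extracellular matrix genes were lower, at −0.40 [−0.44, −0.28] (percentile 0.0800, 1 of 19 higher, 4 lower), Sparc by 2.55-fold [2.19, 2.97] and Thbs1 by 2.25-fold [1.42, 3.62]. Immediate early genes stood at −0.34 [−0.43, −0.24] (below all 10000, 2 of 32 higher, 12 lower). Iron handling stood at 0.14 [0.028, 0.23] (percentile 77.9, 1 of 10 higher, 1 lower), with transferrin, Trf, 5.17-fold [3.87, 6.98] lower and its receptor Tfrc 1.65-fold [1.51, 1.81] higher. Transporters stood at 0.038 [0.0074, 0.097] (percentile 58.0, 2 of 35 higher, 1 lower), the p53 list at −0.031 [−0.054, 0.11] (percentile 23.5, 6 of 47 higher, 3 lower) and Y-linked genes at −0.33 [−0.39, −0.24] (percentile 3.65, 0 of 4 higher, 0 lower). Highest by fold were Catspere2 (6.42 [5.49, 7.55]), Car3 (3.73 [3.25, 4.28]) and Mdk (3.34 [3.096, 3.61]), and lowest, as folds lower, Npas3 (20.4 [17.6, 23.7]), Gbp6 (14.9 [12.2, 18.3]), Iigp1 (12.2 [10.8, 13.9]), Angptl7 (10.7 [9.21, 12.6]) and Vmn1r18 (6.73 [5.81, 7.82]). Mdk, Gbp6, Iigp1 and Angptl7 lead background-like clusters mostly of 1 library. Where the interval left out 0, list directions turned within the Malat1-poor cluster for fatty acid oxidation and iron, within the Malat1-rich cluster for gluconeogenesis and fatty acid oxidation, over all retained barcodes for Hippo and iron, at 20% mitochondrial UMIs or less for transporters, with equal weight of the 2 clusters for iron and after thinning for transporters. Other medians moved by over 1.5-fold within the Malat1-rich cluster for mitotic spindle (0.74) and class II (−2.91) and with at least 100 counts for mitotic spindle (1.12).

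The 2-by-2 design allowed the joint change to be set against the sum of both single changes. Relative to an all-gene value of −0.32, this non-additivity was 0.41 [0.24, 0.61] (percentile 98.4) for HIF targets, 0.90 [0.67, 1.55] (above all 10000) for the mitotic spindle and 0.011 [−0.22, 0.14] (percentile 44.2) for p53. The spindle value rests on few WT and Rassf1a KO counts and was 0.33 without the cluster led by Top2a, 0.12 within the Malat1-rich cluster and 1.78 within the Malat1-poor one. That of HIF targets was 0.096 after thinning, 0.16 over all retained barcodes, 0.18 with equal weight of the 2 clusters and 0.20 within the Malat1-rich one.

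Across 10170 genes, which are not independent replicates, the log2 ratios of Vhl loss in the 2 backgrounds correlated at r = −0.227 (rho = −0.360). Those of Rassf1a loss correlated at r = −0.400 (rho = −0.510). The paired ratios share no library. The value for Vhl turned to 0.0570 within the Malat1-rich cluster, 0.0519 within the Malat1-poor one and 0.0412 with equal weight, and that for Rassf1a lay nearer 0, at −0.168, −0.0440 and −0.128 in the same order. Genes higher with Vhl loss in both backgrounds were led by Cyp2d12, at 2.88-fold [2.31, 3.62] and 2.95-fold [2.73, 3.20], the lysosomal galactosidase Glb1, at 1.91-fold [1.65, 2.22] and 2.23-fold [2.08, 2.405], and the clock repressor Nr1d2, at 2.22-fold [1.87, 2.65] and 1.75-fold [1.63, 1.89]. Slc6a19, Med21, Tef, Hsd3b2, Keg1 and Dhx40 followed, with the smaller of each pair of ratios down to 1.47. Lower in both were Npas3 and Angptl7, then Dmgdh, at 1.66-fold [1.41, 1.97] and 1.66-fold [1.53, 1.81] lower, Npas2, Eprs, Col6a6, Apob, Dnase1 and Ly6a. Nr1d2, Tef and Npas2 are clock genes, whose 2 phases also lay apart in non-proximal cells of the double KO against WT, by 2.36 [1.62, 3.14]. Apob turned in Vhl KO against WT after thinning, within the Malat1-poor cluster and over all retained barcodes, and Col6a6 turned in the double KO against Rassf1a KO within the Malat1-poor cluster.

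Genes higher with Rassf1a loss in both backgrounds were led by the glutamate receptor gene Grid1, at 4.42-fold [3.47, 5.71] and 2.01-fold [1.75, 2.31], and the phosphodiesterase Pde1a, at 1.91-fold [1.76, 2.08] and 2.97-fold [2.79, 3.17]. Fnip2, Tef, Pcdh17, Them7, Uap1, Nceh1 and the chaperone Hspa5, at 1.34-fold [1.27, 1.41] and 1.40-fold [1.33, 1.47], followed. Grid1 turned within the Malat1-poor cluster and Hspa5 within the Malat1-rich cluster in the double KO against Vhl KO. In Rassf1a KO against WT, Fnip2 turned within the Malat1-poor cluster and Pcdh17 over all retained barcodes. Lower in both were Il31ra and Gstp1, then Phb, S100g, Cd44, Acot1, Kpna1, Cmss1 and Pbld2. Il31ra and Gstp1 lead background-like clusters, as do Cd44 and Cmss1 with Vhl KO clustered alone and Cd44 at resolution 2.0. The hyaluronan receptor Cd44 was 2.32-fold [2.09, 2.58] and 1.61-fold [1.47, 1.76] lower. S100g turned in Rassf1a KO against WT once the background was subtracted, which left no WT count.

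**Figure D3:**
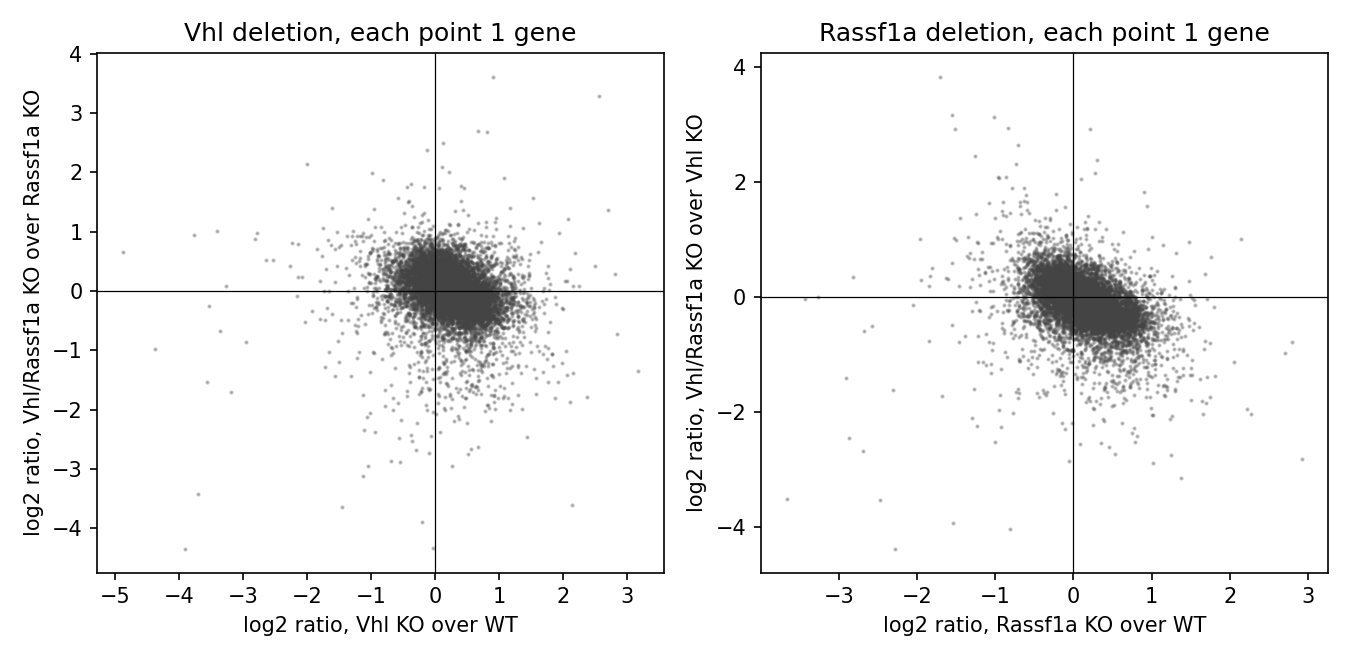
Log2 ratios of each deletion in the 2 backgrounds, 1 point per gene with at least 20 counts in each of the 4 sums. Pearson's r was −0.227 for Vhl and −0.400 for Rassf1a, and within the Malat1-rich and Malat1-poor clusters the first turned and the second was −0.168 and −0.0440.

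Per cell, the HIF target Vegfa was seen in 12.1% [8.10, 17.1] in WT, 18.8% [16.4, 21.4] in Vhl KO, 13.8% [11.8, 15.9] in Rassf1a KO and 12.0% [10.9, 13.1] in the double KO of proximal tubule-like cells thinned to 1000 UMIs. The same depth gave 13.7% [12.96, 14.4] in WT, 7.91% [5.03, 11.7] in Vhl KO, 9.86% [9.41, 10.3] in Rassf1a KO and 8.40% [7.22, 9.70] in the double KO of background-like barcodes. Median depths before thinning were 15426.5, 5519, 15119, 7327.5 and 1307, 1163.5, 1499, 1152.5 UMIs in the same order. Without thinning the shares in proximal tubule-like cells were 68.4% [62.0, 74.4] in WT, 54.0% [50.9, 57.1] in Vhl KO, 68.0% [65.2, 70.7] in Rassf1a KO and 52.3% [50.6, 53.9] in the double KO. Thinned shares in WT did not exceed the background there. Car9, Slc2a1, Ndufa4l2, Havcr1, Cdkn1a, Mki67 and Top2a lay near 1 UMI or near the background-like share, and no difference is read from them.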

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

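The tests of the male-biased and GTPase patterns were chosen only after the results were seen. List medians (log2, relative to all genes) lay on opposite sides of 0 in the 2 backgrounds, with both counting intervals leaving out 0. With 1 library per genotype these differences were not tested. For Vhl loss, the values with Rassf1a intact and with Rassf1a deleted were opposite for gluconeogenesis (−0.36 and 0.25), fatty acid oxidation (−0.36 and 0.23), oxidative phosphorylation (−0.40 and 0.44), transporters (−0.27 and 0.038), YAP and TAZ (0.13 and −0.38), Hippo (0.16 and −0.083), immediate early (0.28 and −0.34), iron (−0.26 and 0.14), sex-linked (0.27 and −0.33), male-biased (−1.72 and 0.83), female-biased (1.38 and −0.47) and sterol (−0.31 and 0.47). For Rassf1a loss, the values with Vhl intact and with Vhl deleted were opposite for HIF targets (−0.19 and 0.24), gluconeogenesis (−0.18 and 0.40), fatty acid oxidation (−0.23 and 0.23), lipid storage (−0.30 and 0.24), oxidative phosphorylation (−0.38 and 0.46), YAP and TAZ (0.28 and −0.36), Hippo (0.20 and −0.15), interferon (0.23 and −0.26), unfolded protein response (−0.24 and 0.41), iron (−0.14 and 0.21), sex-linked (0.31 and −0.20), male-biased (−0.80 and 1.91), female-biased (0.45 and −0.86), sterol (−0.51 and 0.47) and GTPases (1.22 and −1.32). Both values lay on 1 side of 0, for Vhl loss within the Malat1-rich cluster for gluconeogenesis and fatty acid oxidation, within the Malat1-poor one for fatty acid oxidation, oxidative phosphorylation, immediate early and sex-linked, with equal weight of both for iron, over all retained barcodes for Hippo and iron, at 20% mitochondrial UMIs or less for transporters, after thinning for transporters and YAP and TAZ, and for Rassf1a loss within the Malat1-rich cluster for lipid storage and unfolded protein response, within the Malat1-poor one for gluconeogenesis, fatty acid oxidation and lipid storage, with equal weight of both for lipid storage and iron, over all retained barcodes for gluconeogenesis, fatty acid oxidation, interferon and iron, after thinning for HIF targets and unfolded protein response. With no minimum count, HIF targets, gluconeogenesis, Hippo, iron and sex-linked did so for Rassf1a loss too, but lay on opposite sides again with genes that had no count in 1 sum left without limit, not at the floor of 3 counts. Outside the retained barcodes, those with over 50% mitochondrial UMIs made up 34.4% in Vhl KO, 3.89% in Rassf1a KO and 28.3% in the double KO, against 0.893% in WT.

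Male-biased kidney genes were lower in Vhl KO than in WT, and the values here are log2 ratios not set relative to all genes. RNA of female animals would have lowered the Y-linked genes, whose median was 0.55 [0.41, 0.66], and subtraction of the background-like profile left the male-biased list at −1.78 [−1.91, −1.66], which argues against free RNA. An effect of Vhl deletion in either background is argued against by the double KO against Rassf1a KO, at 0.81 [0.77, 0.92]. Fewer S3 cells stay open, since 5 S3 markers outside the list, without the still lower Slc7a13, stood at −0.95 [−1.03, −0.88]. An effect of Vhl loss that depends on Rassf1a, and hormone levels or other differences between the animals, may also account for it and were not tested.

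Interferon-gamma-inducible GTPases were higher in Rassf1a KO than in WT. Markers of T cells, NK cells, macrophages and dendritic cells, cells that the lectin sort should have removed, summed to 16.6 CPM in Rassf1a KO against 6.76 in WT, and the GTPases to 371 against 132, so both were higher. The markers reached 4.47% [3.96, 5.03] of the level of the GTPases, and within the Malat1-poor cluster, where the GTPase median relative to all genes was 3.02 (log2), macrophage and monocyte markers stood at 2.04 against 1.76 CPM, which argues against RNA of immune cells as the whole source. The median was 0.28 within the Malat1-rich cluster and 1.89 [1.60, 2.16] (not relative to all genes) with equal weight of both, which argues against their mix alone but leaves a difference mostly in the Malat1-poor one, and the double KO against Vhl KO, at −1.45 [−1.65, −0.82], argues against an effect of Rassf1a deletion in either background. An effect that depends on Vhl, or an exposure of these animals to interferon, may account for it and was not tested.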

How the results depend on the processing

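The alternatives within or across the 2 proximal tubule-like clusters, with background subtracted, without the 20 most abundant genes and without the cluster led by proliferation markers were chosen after seeing the data, and the other tests of settings before the data were examined. No paired analysis was possible because the barcodes carry no replicate number and no result comes from a test between samples. The cause of a move was not tested unless stated. Of 96 list medians, all kept their values within their counting intervals with TMM factors, DESeq2 size factors, the total with mitochondrial genes and the total without the 20 most abundant genes, since 1 factor per library cancels in a median relative to all genes. Those scalings moved 68, 68, 1 and 37 of 267 named-gene ratios beyond their intervals and turned none. A minimum of 1000 UMIs kept 99 of 100 results. Values below are log2, relative medians of lists that left their counting interval and ratios of named genes that turned, all against WT unless another library is named, and a star marks a direction that turned in a median whose interval left out 0.

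All retained barcodes left 37 of 96 results within their intervals, moved 53 and turned 6, and of 267 named-gene ratios 110, 151 and 6. Glycolysis 0.20, mitochondrially encoded genes −0.047, mitotic spindle 0.66, YAP and TAZ 0.36, unfolded protein response (UPR) −0.56, male-biased −1.37 and female-biased 0.67 were the values for Vhl KO. Glycolysis −0.17, gluconeogenesis 0.057*, fatty acid oxidation (FAO) 0.052*, oxidative phosphorylation (OXPHOS) −0.12, YAP and TAZ 0.12, Hippo 0.098, interferon −0.0094*, class II 0.58, NRF2 −0.13, UPR −0.022, iron 0.045*, male-biased −0.23, sterol −0.34 and GTPases 0.73 were those for Rassf1a KO. Gluconeogenesis 0.16, transporters 0.21, tubule transcription factors 0.39, injury −0.94, cell cycle 0.30, YAP and TAZ −0.034 and interferon −1.34 were those for the double KO. Gluconeogenesis 0.52, OXPHOS 0.35, injury −1.56, mitotic spindle 0.32, YAP and TAZ −0.47, interferon −0.93, immediate early −0.92, iron 0.094, sex-linked −0.068, male-biased 1.77, female-biased −0.57, sterol 0.60 and GTPases −1.68 were those for it against Vhl KO. HIF targets 0.19, glycolysis 0.25, gluconeogenesis 0.073, FAO 0.037, OXPHOS 0.0068, mitotic spindle 1.25, cell cycle 0.38, YAP and TAZ −0.055, Hippo 0.0083*, interferon −1.15, extracellular matrix −0.15, immediate early −0.59, iron −0.049*, sex-linked −0.044, male-biased 0.53 and female-biased −0.30 were those for it against Rassf1a KO. HIF targets 0.16 and mitotic spindle 0.34 were the non-additivity. Named genes that turned were Apob 0.030 in Vhl KO, Adm −0.39, Ccnb2 0.29, Pcdh17 −0.38 and Zeb1 −0.22 in Rassf1a KO, Adm −0.024 in the double KO.

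Thinning to 1000 UMIs left 34 of 96 results within their intervals, moved 54 and turned 8, and of 250 named-gene ratios 78, 153 and 5, with 14 bounds that set no direction. HIF targets 0.077, glycolysis 0.085, gluconeogenesis −0.21, FAO −0.0092, OXPHOS −0.25, mitochondrially encoded genes −0.40, transporters −0.092, mitotic spindle −0.11, YAP and TAZ −0.13*, interferon −0.77, NF-kB −0.14, UPR −0.44, sex-linked 0.51, male-biased −1.18 and female-biased 0.49 were the values for Vhl KO. HIF targets 0.013*, glycolysis −0.25, FAO −0.16, lipid storage −0.031, OXPHOS −0.27, p53 −0.20, interferon −0.067*, class II 0.67, NRF2 −0.17, UPR 0.036*, sex-linked 0.58, male-biased −0.53 and GTPases 1.67 were those for Rassf1a KO. Gluconeogenesis 0.17, injury −0.34, p53 −0.25, mitotic spindle −0.42*, cell cycle 0.37, YAP and TAZ −0.52, interferon −0.41, Arntl phase −0.92 and Nr1d1 phase 0.22 were those for the double KO. HIF targets 0.097, gluconeogenesis 0.30, FAO 0.020, OXPHOS 0.40, injury −0.40, mitotic spindle 0.11, interferon 0.12*, class II −0.31, sex-linked −0.34 and male-biased 1.76 were those for it against Vhl KO. HIF targets 0.17, FAO 0.11, transporters −0.037*, p53 −0.14, mitotic spindle −0.16*, cell cycle 0.50, Hippo −0.21, interferon −0.39, class II −0.94, immediate early −0.64, iron 0.29, male-biased 0.73 and female-biased −0.23 were those for it against Rassf1a KO. HIF targets 0.096 and mitotic spindle 0.15 were the non-additivity. Named genes that turned were Apob 0.28 and Kdm5d −0.29 in Vhl KO, Cxcl10 −0.0032 in Rassf1a KO, Cd74 0.57 in the double KO, Vhl −0.22 in the double KO against Rassf1a KO. The bounds, from genes with no thinned count in the second sum, were for Cdkn1a in Vhl KO, Ciita, H2-Aa and Pfkp in Rassf1a KO, Anln, Birc5, Cdc20, Cry1, Kif11, Rrm2, Slc22a13 and Top2a in the double KO, Aldoc and Anln in the double KO against Rassf1a KO. Turned medians with under 50% of the members, which without thinning stood at the value given, were interferon in Rassf1a KO (8 of 32, 0.11), mitotic spindle in the double KO (8 of 35, 0.25), interferon in it against Vhl KO (9 of 26, 0.013) and mitotic spindle in it against Rassf1a KO (9 of 36, −0.054). In the double KO 2 of those 8 spindle members had no WT count, and left without limit they gave −0.097.

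The 20% mitochondrial limit left 74 of 100 results within their intervals, moved 24 and turned 2, and of 267 named-gene ratios 203, 64 and 0. Mitochondrially encoded genes −0.75 and transporters −0.42 were the values for Vhl KO. OXPHOS −0.49, Hippo 0.32, NRF2 −0.44 and iron −0.26 were those for Rassf1a KO. Gluconeogenesis 0.013, transporters −0.041*, mitotic spindle 0.79 and interferon −1.28 were those for the double KO. Gluconeogenesis 0.28, OXPHOS 0.38, class II −1.26, UPR 0.18, immediate early −0.92, iron 0.14, male-biased 1.76 and female-biased −1.42 were those for it against Vhl KO. Gluconeogenesis 0.16, FAO 0.12, transporters −0.036*, mitotic spindle 1.32, extracellular matrix −0.47, male-biased 0.68 and sterol 0.39 were those for it against Rassf1a KO.

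A minimum of 100 counts left 82 of 98 results within their intervals, moved 16 and turned 0. Mitochondrially encoded genes −0.27 and iron −0.17 were the values for Vhl KO. Glycolysis −0.33 and male-biased −0.84 were those for Rassf1a KO. Injury −0.36, mitotic spindle 0.83 and interferon −0.59 were those for the double KO. OXPHOS 0.43, injury −0.57 and mitotic spindle 0.34 were those for it against Vhl KO. HIF targets 0.21, p53 −0.072 and mitotic spindle 1.12 were those for it against Rassf1a KO. Mitotic spindle 0.36 was the non-additivity. A minimum of 100 counts gave correlations between backgrounds of −0.401 for Vhl and −0.519 for Rassf1a.

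No minimum count left 49 of 96 results within their intervals, moved 47 and turned 0. OXPHOS −0.36, mitochondrially encoded genes −0.26, mitotic spindle 0.86, interferon −0.83 and male-biased −1.51 were the values for Vhl KO. HIF targets 0.0067, glycolysis −0.31, gluconeogenesis 0.037, FAO −0.015, OXPHOS −0.17, p53 0.18, YAP and TAZ 0.47, Hippo 0.40, class II 0.61, NRF2 −0.17, UPR −0.054, iron 0.058, sex-linked 0.48, male-biased −0.58 and sterol −0.30 were those for Rassf1a KO. HIF targets 0.25, glycolysis 0.32, gluconeogenesis 0.26, transporters 0.28, tubule transcription factors 0.27, injury −0.84 and p53 0.19 were those for the double KO. HIF targets 0.38, gluconeogenesis 0.61, FAO 0.44, lipid storage 0.40, OXPHOS 0.67, injury −0.63, p53 0.12, YAP and TAZ −0.19, Hippo 0.021, UPR 0.58, immediate early −0.55, iron 0.33, sex-linked 0.17, female-biased −0.67 and sterol 0.69 were those for it against Vhl KO. Gluconeogenesis 0.31, FAO 0.29, OXPHOS 0.50, YAP and TAZ −0.32 and sex-linked −0.20 were those for it against Rassf1a KO. With genes of no count in 1 sum left without limit, not at the floor, medians whose sign the floor had changed were HIF targets −0.25, gluconeogenesis −0.23, iron −0.17 in Rassf1a KO and Hippo −0.18, sex-linked −0.034 in the double KO against Vhl KO.

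The Malat1-rich cluster left 45 of 98 results within their intervals, moved 45 and turned 8, and of 265 named-gene ratios 147, 113 and 5. Glycolysis −0.35, gluconeogenesis −0.39, OXPHOS −0.64, mitochondrially encoded genes −0.18, transporters −0.100, interferon −0.74, NF-kB −0.13, immediate early 0.42 and male-biased −1.28 were the values for Vhl KO. Glycolysis −0.23, FAO −0.094, interferon 0.0087, male-biased −0.52 and GTPases 0.28 were those for Rassf1a KO. HIF targets −0.0083*, glycolysis −0.19*, gluconeogenesis −0.22*, transporters 0.0069, injury −0.30, mitotic spindle 0.58 and cell cycle 0.37 were those for the double KO. HIF targets 0.096, gluconeogenesis 0.17, FAO 0.14, lipid storage −0.074*, OXPHOS 0.28, injury −0.53, mitotic spindle 0.098, UPR −0.097*, iron 0.077, sex-linked −0.10, male-biased 1.71, female-biased −1.84 and sterol 0.13 were those for it against Vhl KO. HIF targets 0.14, glycolysis 0.15, gluconeogenesis −0.079*, FAO −0.038*, OXPHOS 0.056, mitotic spindle 0.74, cell cycle 0.37, YAP and TAZ −0.24, interferon −0.59, class II −2.91, extracellular matrix −0.19, iron 0.0050, sex-linked −0.074, male-biased 0.65 and sterol 0.22 were those for it against Rassf1a KO. HIF targets 0.20 and mitotic spindle 0.12 were the non-additivity. Named genes that turned were Apoe −0.14 and Cxcl10 −0.41 in Rassf1a KO, Khk −0.10 in the double KO, Hspa5 −0.13 and Rassf1 0.031 in the double KO against Vhl KO. Correlations between backgrounds were 0.0570* for Vhl and −0.168 for Rassf1a.

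The Malat1-poor cluster left 35 of 98 results within their intervals, moved 47 and turned 16, and of 264 named-gene ratios 97, 156 and 11. Glycolysis 0.36, gluconeogenesis −0.052, FAO −0.0023, OXPHOS 0.099*, mitochondrially encoded genes −0.44, transporters −0.70, p53 0.29, interferon 0.29*, immediate early −0.020*, iron 0.11*, sex-linked −0.21*, male-biased −2.26 and female-biased 0.69 were the values for Vhl KO. Glycolysis −0.21, gluconeogenesis 0.057*, FAO −0.065, lipid storage 0.11*, OXPHOS −0.037, interferon 1.83, class II 0.95, NRF2 0.040*, UPR −0.027, iron 0.11*, sex-linked −0.090*, male-biased −0.72, female-biased 1.60, sterol −0.23 and GTPases 3.02 were those for Rassf1a KO. Glycolysis 0.20, gluconeogenesis 0.19, transporters 0.020, YAP and TAZ 0.0038, interferon −0.20 and Arntl phase −0.51 were those for the double KO. HIF targets 0.34, gluconeogenesis 0.20, FAO −0.016*, OXPHOS 0.014, injury −1.40, class II −1.53, UPR 0.53, immediate early −1.02, iron −0.00037*, sex-linked 0.13* and female-biased −0.099 were those for it against Vhl KO. Glycolysis 0.40, gluconeogenesis 0.12, FAO −0.0031*, OXPHOS 0.12, transporters 0.0069, cell cycle 0.42, YAP and TAZ −0.32, interferon −2.48, class II −1.57, immediate early −0.44, iron −0.16*, sex-linked −0.13, male-biased 0.55 and female-biased −0.98 were those for it against Rassf1a KO. The p53 list −0.27 and mitotic spindle 1.78 were the non-additivity. Named genes that turned were Apob 0.13, Cycs 0.00065, Tmem108 −0.43, Trpm3 −2.81 and Zeb1 −0.17 in Vhl KO, Fnip2 −0.031 and Nfkbiz −0.32 in Rassf1a KO, Gbp2 0.29 and Grid1 −0.35 in the double KO against Vhl KO, Col6a6 0.28 and Rassf1 0.0080 in the double KO against Rassf1a KO. Correlations between backgrounds were 0.0519* for Vhl and −0.0440 for Rassf1a.

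Equal weight left 53 of 98 results within their intervals, moved 41 and turned 4, and of 267 named-gene ratios 176, 91 and 0. Glycolysis 0.15, gluconeogenesis −0.24, FAO −0.14, OXPHOS −0.10, mitochondrially encoded genes −0.35, iron −0.092 and sex-linked 0.12 were the values for Vhl KO. Glycolysis −0.27, gluconeogenesis −0.061, FAO −0.078, lipid storage −0.049, OXPHOS −0.15, YAP and TAZ 0.18, interferon 0.57, class II 0.65, NRF2 −0.14, UPR −0.094, male-biased −0.72 and GTPases 1.75 were those for Rassf1a KO. Gluconeogenesis 0.32, FAO 0.0094, lipid storage −0.050*, OXPHOS 0.065, injury −1.10, class II −1.51, UPR 0.27, iron −0.014*, sex-linked −0.011, female-biased −0.70 and sterol 0.19 were those for it against Vhl KO. Glycolysis 0.31, gluconeogenesis 0.088, FAO 0.012, OXPHOS 0.084, cell cycle 0.39, YAP and TAZ −0.27, interferon −2.04, class II −1.76, extracellular matrix −0.24, iron −0.058*, sex-linked −0.093 and male-biased 0.52 were those for it against Rassf1a KO. HIF targets 0.18 was the non-additivity. Correlations between backgrounds were 0.0412* for Vhl and −0.128 for Rassf1a.

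Background subtraction left 61 of 98 results within their intervals, moved 35 and turned 2, and of 265 named-gene ratios 171, 91 and 3. HIF targets −0.17, glycolysis −0.22, gluconeogenesis −0.46, FAO −0.54, OXPHOS −0.76, mitochondrially encoded genes −0.22, UPR −0.97, iron −0.46 and male-biased −2.10 were the values for Vhl KO. Glycolysis −0.57, gluconeogenesis −0.25, FAO −0.32, OXPHOS −0.59, NRF2 −0.46, UPR −0.30, male-biased −0.97 and sterol −0.63 were those for Rassf1a KO. Glycolysis −0.14*, gluconeogenesis −0.11*, transporters 0.12, injury −0.76, cell cycle 0.35 and Arntl phase −0.99 were those for the double KO. Lipid storage 0.10, OXPHOS 0.31 and sterol 0.25 were those for it against Vhl KO. Glycolysis 0.52, gluconeogenesis 0.16, FAO 0.12, OXPHOS 0.22, YAP and TAZ −0.28, extracellular matrix −0.27, sex-linked −0.19, female-biased −0.94 and sterol 0.40 were those for it against Rassf1a KO. Named genes that turned were Lrp1b 3.37 in Vhl KO, S100g 2.93 and Sec61a1 5.39 in Rassf1a KO. Correlations between backgrounds were −0.142 for Vhl and −0.302 for Rassf1a.

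Leaving out the cluster led by proliferation markers, which lowers these lists in part by construction, left 3 of 8 results within their intervals, moved 5 and turned 0. Mitotic spindle was 0.79 for the double KO, 0.014 for it against Vhl KO and 0.62 for it against Rassf1a KO. Cell cycle was 0.44 in the last, and mitotic spindle 0.33 in the non-additivity.

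Spearman's rho in place of Pearson's r gave −0.360 for Vhl and −0.510 for Rassf1a. The proximal tubule-like share was 0.800% in WT, 13.5% in Vhl KO, 3.24% in Rassf1a KO and 14.5% in the double KO with resolution 0.5, where 1 cluster alone met the naming rule. It was 0% in WT, 25.8% in Vhl KO, 3.20% in Rassf1a KO and 43.6% in the double KO with each matrix clustered alone. No WT cluster then met the rule. The share was 35.3% in the double KO with resolution 2.0. Retained barcodes were 1673 in Vhl KO with at least 1000 UMIs and 7669 with no filter. The double KO kept 5673 with at most 20% mitochondrial UMIs.

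Shares of proximal tubule-like cells with a UMI move with the depth by construction. Without thinning those outside the interval at 1000 UMIs were Car9 4.82% in WT, 3.81% in Vhl KO, 4.96% in Rassf1a KO and 4.57% in the double KO, Vegfa 68.4% in WT, 54.0% in Vhl KO, 68.0% in Rassf1a KO and 52.3% in the double KO, Slc2a1 12.3% in WT, 4.004% in Vhl KO, 9.84% in Rassf1a KO and 5.10% in the double KO, Havcr1 3.95% in WT, 2.13% in Rassf1a KO and 2.62% in the double KO, Cdkn1a 3.51% in WT, 4.30% in Vhl KO, 3.28% in Rassf1a KO and 3.35% in the double KO, Mki67 1.66% in Vhl KO, 1.15% in Rassf1a KO and 2.17% in the double KO, Top2a 1.46% in Vhl KO, 0.798% in Rassf1a KO and 2.17% in the double KO. At 500 UMIs those outside that interval were Vegfa 7.02% in WT, 8.89% in Vhl KO, 7.45% in Rassf1a KO and 6.66% in the double KO, Car9 0% in Vhl KO and 0.279% in the double KO, Slc2a1 0.293% in Vhl KO, 0.355% in Rassf1a KO and 0.279% in the double KO, Top2a 0% in Rassf1a KO, Havcr1 0.223% in the double KO, Mki67 0.279% in the double KO. At 2000 UMIs those outside that interval were Vegfa 21.7% in WT, 31.1% in Vhl KO, 23.1% in Rassf1a KO and 21.9% in the double KO, Car9 1.13% in Vhl KO and 1.59% in the double KO, Slc2a1 2.01% in Rassf1a KO and 1.36% in the double KO, Top2a 0% in Rassf1a KO and 0.936% in the double KO, Havcr1 0.851% in the double KO, Cdkn1a 1.30% in the double KO, Mki67 1.05% in the double KO.

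Depth limits these results through the WT sum, the smallest of the 4, and through thinned levels near 1 UMI, from which no change is read. Leaving out each replicate, the tests by edgeR and DESeq2 and the fit with a replicate block were not run, since no barcode maps to a replicate. Leaving out injured clusters was not run because the naming rule had no such class, and keeping doublet calls changed nothing because none was removed. Named genes without a value under an alternative are not in its counts.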

Other observations

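The test of nuclear RNA was chosen only after the result was seen, and that of the collection hour before its value was seen. Clock genes, 2 lists added after the data were seen, moved in opposite directions in the double KO against WT. Genes that peak with Arntl were lower, at −1.19 [−1.38, −0.999] (below all 10000, 0 of 6 higher, 3 lower) relative to all genes, Npas2 by 3.11-fold [2.78, 3.47] and Cry1 by 3.78-fold [2.54, 5.60]. Genes that peak with Nr1d1 were higher, at 0.86 [0.60, 1.24] (above all 10000, 7 of 10 higher, 0 lower), the output factor Dbp by 7.29-fold [4.13, 14.2] and the repressor Nr1d1 by 3.17-fold [2.39, 4.29]. The first median was −0.51 within the Malat1-poor cluster and the second 0.22 after thinning.

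Sterol biosynthesis genes, also a list added after the data were seen, stood at −0.31 [−0.53, −0.11] (percentile 1.65, 0 of 15 higher, 1 lower) in Vhl KO and −0.51 [−0.62, −0.36] (below all 10000, 0 of 15 higher, 2 lower) in Rassf1a KO against WT. In the double KO they were higher than in Vhl KO, at 0.47 [0.29, 0.58] (above all 10000, 5 of 15 higher, 0 lower), and than in Rassf1a KO, at 0.47 [0.40, 0.68] (above all 10000, 7 of 15 higher, 0 lower). Cyp51, a demethylase of this pathway, was 2.27-fold [1.98, 2.62] and Idi1, an isoprenoid isomerase, 1.91-fold [1.66, 2.20] of Vhl KO.

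The clock pattern was set against a technical and a collection difference. Within the Malat1-rich cluster the Nr1d1-phase median less the Arntl-phase median was 2.18 [1.90, 2.65] (log2), which argues against the share of nuclear RNA. In non-proximal cells the same difference was 2.36 [1.62, 3.14], and a different hour of kidney collection is a candidate explanation. It rests on 34 WT cells, of which 6 lay in a sub-cluster led by endothelial genes, 5 in a background-like one, 3 in one led by smooth muscle genes and 2 in one led by Fst and Lyz2, and free RNA from proximal tubule and an effect of the deletions in those cells stay open.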
